A study of Mus musculus with 2 samples.

How the data were processed

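Lung mesenchymal cells of Lepr-CreERT2;Rosa26-tdTomato mice aged 8 to 10 weeks were profiled by droplet single-cell RNA sequencing after saline or bleomycin, with 1 library per treatment. In these mice a tamoxifen-dependent Cre recombinase is made from the leptin receptor gene and switches on the red fluorescent protein tdTomato for good, so a marked cell stays marked after Lepr itself is switched off. Per the labels' protocols, lungs were digested with collagenase, dispase and DNase, red blood cells were lysed, and live tdTomato-positive cells lacking CD45, EpCAM and CD31 were sorted, a gate set against leukocytes, epithelial cells and endothelial cells. The number of mice behind each library, the dose of bleomycin, the day of collection and the timing of tamoxifen are not given in the sources used here.

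The deposited matrices hold raw UMI counts (unique transcript molecules) per gene and cell barcode, from the 3' kit of 10x Genomics in its v3 chemistry per the labels' protocols, and made with Cell Ranger 6.1.2 on the mouse build mm10 per the submitters' processing notes. The counts were checked to be whole numbers, and no feature for tdTomato or Cre was among the 32285 genes. Gene positions were taken from the GENCODE annotation of the same build by gene identifier, with 32235 identifiers matched. Cell classes were rebuilt from the counts, and no annotation by the authors was used here.

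The saline library held 8396 barcodes with 60937359 UMIs and the bleomycin library 10138 barcodes with 134732429 UMIs. Cells were kept with at least 500 detected genes and at most 10% of UMIs from mitochondrial genes, which left 8350 and 10001 cells. Doublets were called per library with Scrublet as implemented in scanpy 1.11.5 at an expected rate of 7%, and the called cells were left out. It marked 66 saline cells (0.790%) and 0 bleomycin cells, so the caller did not work on the bleomycin library and doublets stay in it. For that reason an alternative without the 5% of cells with the highest doublet scores in each library was added after seeing the data.

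Both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used, and a graph of 15 neighbours was partitioned with the Leiden method at resolution 0.5 (scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0). Clusters were named only from 19 marker lists fixed before the data were examined. A name needed at least 3 markers raised at least 1.5-fold against all other cells with 10 CPM added (CPM being UMIs scaled to a common library total), a median log2 fold of at least 0.5 over the list, and a share of at least 0.5 of the list's members at 10 CPM or more, the last condition set after seeing the data. All 12 clusters reached a name by that rule. The leading genes of the cluster matching the macrophage list were immunoglobulin genes, and those of the cluster matching the alveolar epithelial list included airway genes, so both are described by their genes. Together with the mesothelial cell-like cluster they were left out of the mesenchymal comparisons, which used 8099 saline and 9624 bleomycin cells with 58818930 and 130226589 UMIs. A class was compared between libraries where none of its clusters had more markers of another class than of its own among its top genes, and where each of its clusters held at least 50 cells of each library.

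UMIs were summed per library over all mesenchymal cells, or over a class, and divided by the total to give CPM. With 1 library per group no test of the treatment is possible, so no p-value is given. Shares of cells carry exact Clopper-Pearson intervals, CPM exact Poisson intervals, and ratios of CPM (bleomycin over saline) exact conditional binomial intervals, all at 95% and all covering counting error only. A gene met the size rule when its CPM was at least 2-fold apart, at least 10 CPM in the higher library, and the interval of the ratio lay clear of 1. The rule was tested on simulated counts of all mesenchymal cells with 200 altered genes among 21720. It called 50 of 50 genes at each of the folds 3, 4 and 8, and 0 of 50 at a fold of 1.5. Among the 7352 simulated genes left unaltered it called 0. Both simulated libraries were drawn from 1 pooled profile with counting error alone, so at this depth the fold limit fixed these outcomes. They say nothing of calls caused by differences between animals, preparations or cell mixtures.

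To compare shares of cells with a UMI of Lepr, Cthrc1 or Acta2, or with UMIs of at least 2 genes of the proliferating cell list, every cell was thinned at random to 2000 UMIs. Mesenchymal cells below that depth, 144 in saline and 153 in bleomycin, were left out. The cluster of epithelial and endothelial genes served as background.

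Beside the 19 marker lists, 22 gene lists were fixed before the data were examined. A list's members counted as measured at 10 CPM or more in either library. Each list was given the number of members meeting the size rule, its median log2 ratio, and the percentile of that median among 10000 random lists of the same size drawn from 20 bins of mean expression. The percentile describes these libraries and is not a test. Because the mixture of cells differed between libraries, ratios were also taken after weighting the bleomycin profile of each cluster by that cluster's part of the saline UMIs. This saline mixture was chosen after seeing the data.

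The genes named in the text were set by a rule fixed in advance. Always named were Lepr, any tdTomato or Cre feature, Cthrc1, Acta2, Col1a1, Col3a1, Postn, Saa3, Lcn2, Mki67, Cdkn1a and Pdgfra. The rule added the 12 highest and 12 lowest ratios among genes that met the size rule, reached 20 CPM and lay on 1 side of 1 in every mesenchymal cluster with 50 cells of each library. Predicted genes, ribosomal, mitochondrial and globin genes and markers of non-mesenchymal types were left out of that part. It also took up to 2 members from each end of every list, the 8 highest and 8 lowest within alveolar fibroblast-like cells, and up to 5 leading genes per cluster as its definition only. Tpm3, Fos, Gm8797, Eif3j2, Mpp7, Xist and the other genes of the X and Y chromosomes were named after their values were seen. Members of a list outside the rule are named where they complete a short count.

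Alternatives fixed before the data were examined were scaling by the median of ratios, the mean of per-cell CPM, other CPM and fold minimums, doublets kept, a filter at 1500 genes and 5% mitochondrial UMIs, other depths of thinning, inclusion of all cells, omission of proliferating cells, Leiden resolutions of 0.25 and 1, and clusters made from saline cells alone. Added after seeing the data were the alternatives without the highest doublet scores, with clusters made without the genes meeting the size rule, and with only cells carrying a UMI of Xist. Calculations used numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and anndata 0.12.19, and plots matplotlib 3.10.9. No trajectory, velocity or cell communication analysis was made, since order in time cannot be read from 1 library per treatment.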

Results

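Single-cell transcriptomes were collected from lung mesenchymal cells carrying a permanent tdTomato mark of leptin receptor (Lepr) expression, from mice given saline or bleomycin, a drug that injures the alveolar epithelium and is widely used to model lung fibrosis. Each treatment had 1 library. There is thus no spread between animals to set a difference against, and every statement is about these 2 libraries, with 95% intervals in brackets that cover counting error only. The saline library held 8396 barcodes with 60937359 UMIs, at a median of 6762 UMIs and 2286 genes per barcode. The bleomycin library was deeper, with 10138 barcodes, 134732429 UMIs and medians of 11662 UMIs and 3083 genes. The median share of mitochondrial UMIs was 1.87% in saline and 1.88% in bleomycin. After filtering and removal of called doublets 8284 saline and 10001 bleomycin cells were used.

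The first question was which mesenchymal classes carried the mark in normal and in fibrotic lungs. In saline, 68.1% [67.1–69.1] of marked cells were alveolar fibroblast-like, the lipid- and retinoid-handling fibroblasts of the alveolar wall, against 2.83% [2.51–3.17] in bleomycin. The bleomycin share was 15.6% at clustering resolution 1 and 7.65% under the stricter cell filter. Inflammatory fibroblast-like cells, led by Hp, Saa3 and Lcn2, made up 2.10% [1.80–2.43] of saline and 45.6% [44.6–46.5] of bleomycin cells, and 0.942% and 28.7% at resolution 1. Fibrotic fibroblast-like cells, led by Spp1 and Cthrc1, made up 0.0845% [0.0340–0.174] of saline cells, 7 in number, and 18.9% [18.1–19.7] of bleomycin cells, and 40 saline cells (0.504%) without the 5% highest doublet scores, an alternative chosen after seeing the data. Proliferating cell-like cells were 0.604% [0.448–0.795] of saline and 5.66% [5.21–6.13] of bleomycin cells.

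The remaining mesenchymal classes were closer in size between the libraries in the main clustering. Adventitial fibroblast-like cells, the Pi16-positive fibroblasts around vessels and airways, held 17.6% [16.8–18.5] of saline and 12.1% [11.5–12.8] of bleomycin cells. Peribronchial fibroblast-like cells held 4.93% [4.47–5.41] and 5.90% [5.45–6.38], though 2.22% and 5.93% under the stricter cell filter, and smooth muscle-like cells 4.32% [3.89–4.78] and 5.28% [4.85–5.74]. The genes that set these clusters also differed between the libraries, so the cells were clustered again without the genes meeting the size rule, an alternative chosen after seeing the data. The alveolar share was then 67.1% in saline and 7.70% in bleomycin, the inflammatory share 4.76% and 34.9%, the fibrotic share 0.314% and 25.4%, and the proliferating share 0.459% and 4.06%. Adventitial cells held 15.4% and 11.2%, peribronchial cells 5.00% and 6.13%, and smooth muscle cells 4.36% and 5.39%.

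Of the inflammatory cluster 96.3% and of the fibrotic cluster 99.6% of cells came from the bleomycin library, so with 1 library per treatment each may be that library and not a type. When bleomycin cells were placed among clusters made from saline cells alone, 98.1% of the fibrotic and 86.6% of the inflammatory bleomycin cells fell to saline clusters that matched no marker list. Such unnamed clusters then held 35.5% of saline and 63.1% of bleomycin cells, the inflammatory share was 1.98% and 4.23%, and the alveolar share 33.3% and 3.04%. Of the 2938 saline cells in the unnamed clusters 2708 were alveolar fibroblast-like in the main clustering. The missing name therefore does not show that these bleomycin cells lacked saline counterparts. All shares are of cells within the sorting gate and say nothing of the total number of any class in the lung.

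**Figure D1:**
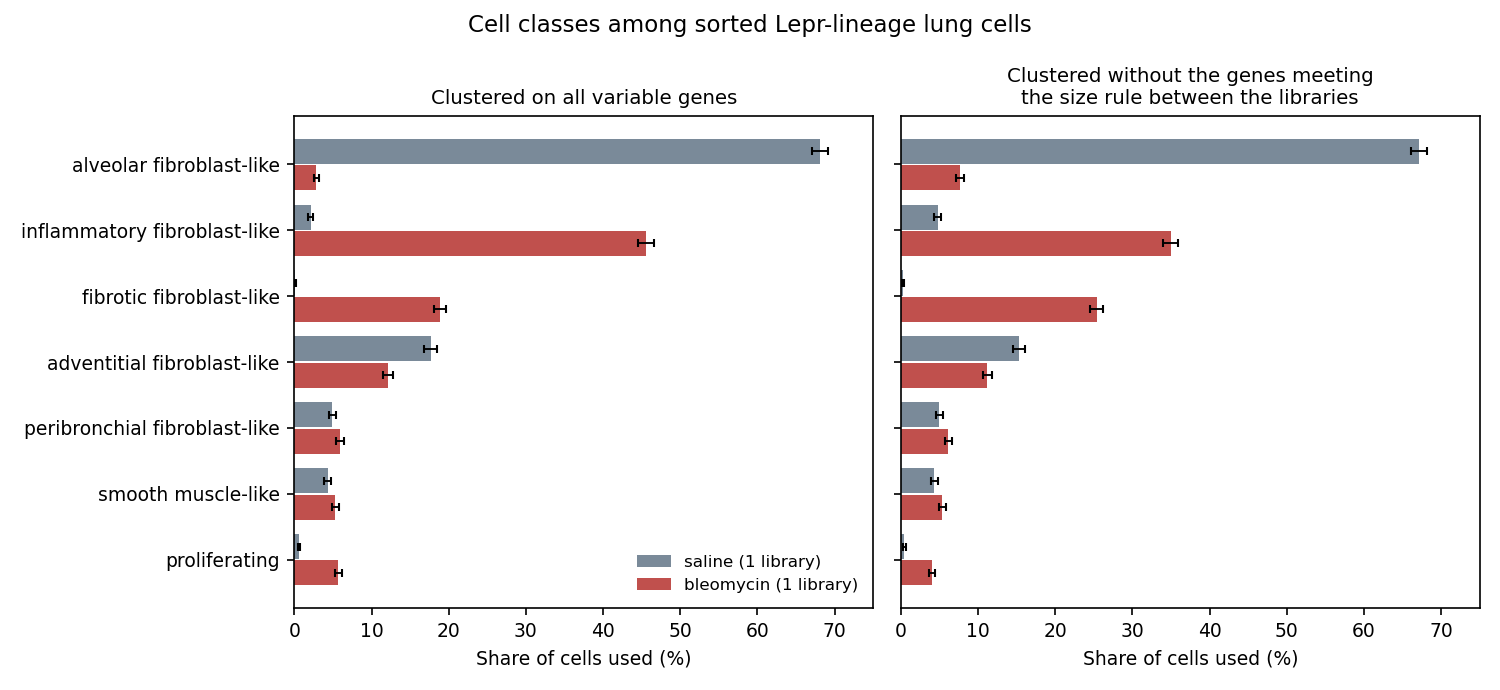
Share of cells in each mesenchymal class as percent of the saline (8284) and bleomycin (10001) cells, with exact 95% binomial intervals as error bars, clustered on all variable genes in 1 panel and without the genes meeting the size rule in the other. In both panels the alveolar fibroblast-like class is larger in saline (68.1% and 67.1%) and the inflammatory and fibrotic fibroblast-like classes are larger in bleomycin.

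Lepr, the gene whose activity had marked the cells, was itself lower in the bleomycin library. It is the receptor of the fat-cell hormone leptin and lies on chromosome 4 from 101717404 to 101815352 of mm10 (identifier ENSMUSG00000057722). Its level over all mesenchymal cells was 62.6 CPM [60.6–64.6] in saline and 11.3 CPM [10.7–11.9] in bleomycin, a ratio of 0.180 [0.170–0.192]. The ratio was below 1 in 8 of the 8 mesenchymal clusters with 50 cells of each library, and at the saline mixture of clusters it was 0.521. At 2000 UMIs per cell, a Lepr UMI was found in 10.99% [10.3–11.7] of saline cells (874 of 7955) and 2.73% [2.42–3.08] of bleomycin cells (259 of 9471). Without thinning the shares were 29.2% and 11.6%, at the unequal depths of the libraries. Among the 8 mesenchymal clusters, the intervals at 2000 UMIs lay apart only in adventitial clusters 5 and 6 and peribronchial cluster 7. In inflammatory cluster 1 the share was 1.75% [0.363–5.04] in saline and 2.17% [1.77–2.64] in bleomycin. Among cells of the cluster with epithelial and endothelial genes, which serve as background, a Lepr UMI was found at 2000 UMIs in 2.59% [0.537–7.37] of saline cells (3 of 116) and in 0 of 158 bleomycin cells, with an upper bound of 2.31%. The median depths of those cells were 5759 and 7380 UMIs. Lepr RNA was thus detected in a minority of the cells it had marked, in both libraries.

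Cells with a UMI of Cthrc1, a secreted glycoprotein of matrix-producing fibroblasts, were almost absent from saline and frequent in bleomycin. At 2000 UMIs the share was 0.101% [0.0434–0.198] in saline and 13.4% [12.7–14.1] in bleomycin, and 0.333% and 25.1% without thinning. The background cluster gave 0 of 116 saline cells, with an upper bound of 3.13%, and 3.16% [1.04–7.23] of bleomycin cells. For Acta2, the smooth muscle actin used as a myofibroblast marker, the share was 23.0% [22.1–24.0] and 41.0% [40.0–42.0] at 2000 UMIs and 36.0% and 64.5% unthinned, with a background of 6.03% and 11.4%. Cells with UMIs of at least 2 proliferation genes made up 1.28% [1.047–1.55] of saline and 7.19% [6.68–7.73] of bleomycin cells, or 6.54% and 18.0% unthinned, against a background of 0.862% and 3.16%.

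Summed over all mesenchymal cells, 445 genes were higher and 473 lower in bleomycin by the size rule, of 8016 genes with at least 10 CPM in either library. Spp1, which encodes the adhesive phosphoprotein osteopontin (chromosome 5, 104435118 to 104441050), was at 2.91 CPM [2.49–3.38] in saline and 7441 CPM [7426–7455] in bleomycin, a ratio of 2559 [2203–2991]. Cthrc1 (chromosome 15, 39076932 to 39087121) was at 0.714 CPM [0.515–0.965] and 262 CPM [260–265], a ratio of 367 [272–510]. Among genes on the same side of 1 in every mesenchymal cluster compared, which leaves out Cthrc1, the 12 highest were Spp1, Kif26b (97.0-fold), the adhesion molecule Chl1 (73.8-fold), the BMP antagonist Grem1 (52.8-fold), the activin antagonist follistatin Fst (43.9-fold), the protease inhibitor Slpi (36.6-fold), the collagenase Mmp8 (29.5-fold), the prostaglandin transporter Slco2a1 (23.3-fold), the hyaluronan-degrading Cemip (20.2-fold), the EGF receptor ligand Ereg (14.9-fold), the anchoring collagen Col7a1 (14.3-fold) and Basp1 (13.0-fold).

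The 12 lowest genes by the same rule were led by Tpm3-rs7, a tropomyosin-related gene on chromosome 14 (113314608 to 113316754), at 101 CPM in saline and 1.88 CPM in bleomycin, 53.7-fold lower. Next came Colq (16.7-fold lower), the amino acid transporter Slc7a10 (13.1-fold), periplakin Ppl (10.7-fold), the splicing factor Cwc22 (10.6-fold; chromosome 2, 77881159 to 77946375), the transcription factor Zbtb16 (9.83-fold) and the microtubule protein Mapt (9.37-fold). Kank3 was 7.43-fold lower, the methyltransferase Inmt 7.42-fold, Mettl7a1 6.64-fold, the interferon-induced GTPase Gbp5 6.32-fold and the sodium channel Scn3a 6.21-fold. Inmt, a very abundant transcript of alveolar fibroblasts, was at 2916 CPM [2902–2930] in saline and 393 CPM [389–396] in bleomycin.

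Most of these differences were smaller once the libraries were set to the same mixture of cells. At the saline mixture of clusters, 85 of the 445 higher genes (19.1%) and 37 of the 473 lower genes (7.82%) were still at least 2-fold apart. Of the 58818930 saline UMIs that set the weights, 40932953 lay in alveolar clusters 2 and 3, where bleomycin had 283 cells. Clusters were made from expression, so bleomycin cells whose state had changed may lie in other clusters. The saline mixture therefore cannot separate a change of mixture from a change of state. Spp1 then had a ratio of 130, Cthrc1 of 37.9, Chl1 of 20.9, Kif26b of 16.9 and Grem1 of 11.5. Inmt had a ratio of 0.758, Slc7a10 of 0.669 and Colq of 0.597, whereas Tpm3-rs7 was at 0.0238, Cwc22 at 0.0910 and Zbtb16 at 0.359. Tpm3-rs7 and Cwc22 were lower in every cluster compared, the epithelial one included. The median log2 ratio of the 6960 genes with at least 10 CPM in both libraries was -0.03.

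**Figure D2:**
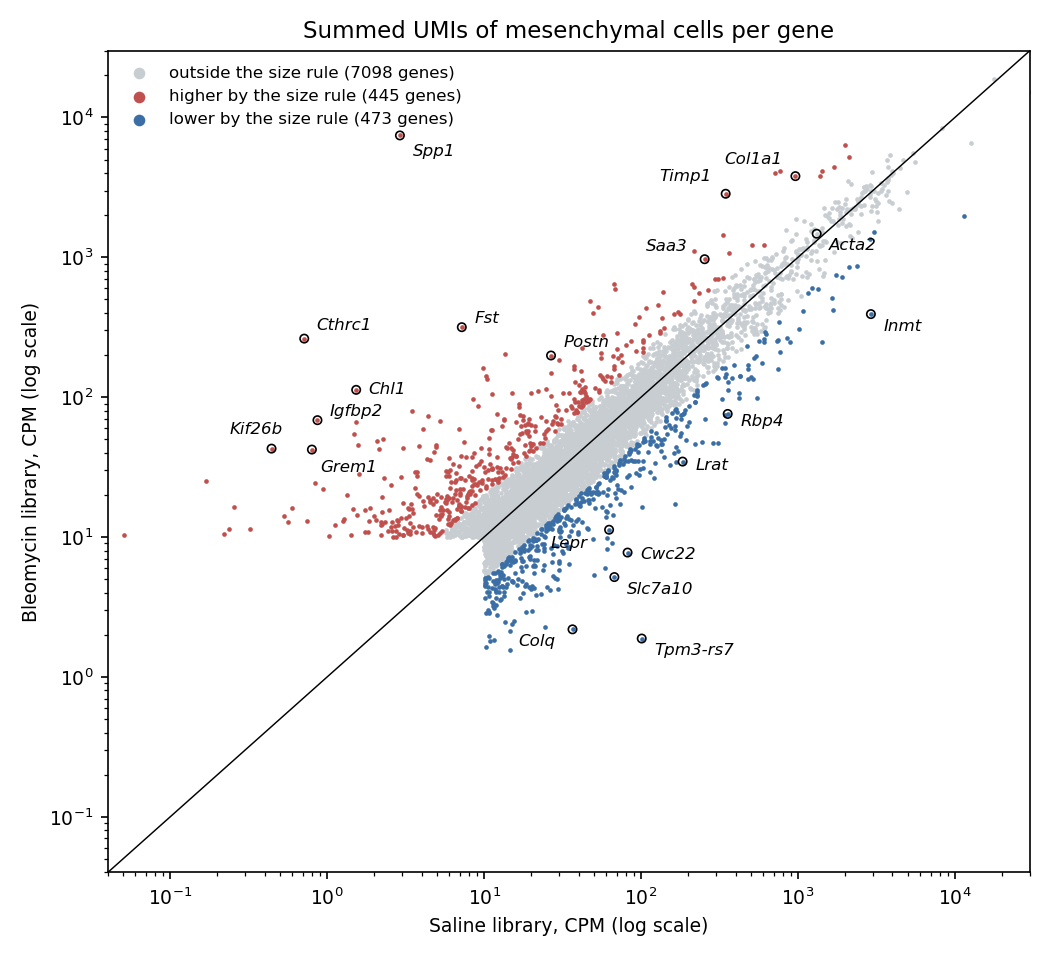
CPM of each gene over all mesenchymal cells in saline (x axis) and bleomycin (y axis), both on logarithmic axes, for the 8016 genes with at least 10 CPM in either library. The 445 genes higher in bleomycin by the size rule are red, the 473 lower ones blue and the other 7098 grey, with Spp1 and Cthrc1 far above the diagonal and Lepr below it.

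Genes of scar-forming fibroblasts and of collagen matrix were higher together in bleomycin. All 12 measured fibrotic fibroblast markers met the size rule as higher, with a median log2 ratio of 3.75, at percentile 100 among matched random lists, and 2.06 at the saline mixture. The smallest ratios among them were those of Runx1 at 2.97-fold [2.87–3.07] and Col12a1 at 4.46-fold. Periostin, Postn, a matrix protein of healing tissue, was at 26.7 CPM [25.4–28.05] in saline and 199 CPM [196–201] in bleomycin, 7.44-fold higher. Of 26 fibrillar matrix genes 17 were higher and 1 lower, with a median log2 ratio of 1.47 at percentile 100, and 0.57 at the saline mixture. Col1a1, a chain of the main scar collagen (chromosome 11, 94936224 to 94953042), was at 963 CPM [955–971] and 3807 CPM [3797–3818], 3.95-fold [3.92–3.99] higher, and Col3a1 was 2.63-fold [2.61–2.64] higher. Fibrillin 2, Fbn2, was 64.6-fold [39.1–116] higher from a saline level of 0.255 CPM, and Col11a1 204-fold [69.6–990] higher from 3 saline UMIs. Fibulin 1, Fbln1, was the lower gene, with a ratio of 0.436, and decorin, Dcn, was at 0.929.

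Some enzymes that modify and cross-link collagen were also higher. Of 21 collagen processing genes 6 were higher, 0 lower and 15 neither, with a median log2 ratio of 0.69 at percentile 100 and 0.23 at the saline mixture, led by the prolyl hydroxylase subunit P4ha3 (8.39-fold) and the procollagen proteinase Bmp1 (3.83-fold), while Pcolce had a ratio of 0.764. Of 21 TGF-beta response genes 4 were higher and 0 lower, with a median of 0.47 at percentile 99.9 and 0.14 at the saline mixture. They were the activin subunit Inhba (16.3-fold), the latency protein Ltbp2 (9.66-fold), Il11 and Tgfb1, while the NADPH oxidase Nox4 had a ratio of 0.530 and Bambi 0.559. Among 16 matrix proteases and inhibitors 5 were higher, namely Timp1 (8.23-fold, at 2848 CPM in bleomycin), Adamts12 (4.36-fold), Ctsk, Mmp14 and Mmp23, with a median of 0.18 at percentile 88.4 and 0.34 at the saline mixture. Of 12 basement membrane genes the collagens Col4a2 (3.59-fold) and Col4a1 (2.37-fold) were higher and nephronectin, Npnt, lower (ratio 0.389), with a median of 0.08 at percentile 64.8 and 0.14 at the saline mixture.

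Few contractile genes met the size rule over all mesenchymal cells. Of 22 actin and contractile genes, Csrp2 (2.71-fold) and the nonmuscle myosin Myh9 (2.18-fold) were higher and 0 lower, with a median log2 ratio of 0.20 at percentile 90.0 and -0.16 at the saline mixture. Acta2 itself (chromosome 19, 34241090 to 34255590) was at 1316 CPM [1307–1325] in saline and 1475 CPM [1468–1482] in bleomycin, a ratio of 1.12 [1.11–1.13] that was 0.701 at the saline mixture. Smooth muscle-like cells held 56303 of the 77413 Acta2 UMIs in saline and 57021 of 192096 in bleomycin, so this sum hides differences between classes. Of the 11 smooth muscle markers 0 met the rule, at a median of -0.15 and percentile 22.2.

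Genes of alveolar fibroblast identity were lower. Of the 12 alveolar fibroblast markers 10 were lower and 0 higher, with a median log2 ratio of -1.41 at percentile 0, and the median was -0.09 at the saline mixture, where a value near 0 is partly set by these markers having named the class. The carboxylesterase Ces1d, at a ratio of 0.549, and Mfap4, at 0.631, missed the rule, and the platelet-derived growth factor receptor Pdgfra was at 0.542 [0.534–0.550]. Retinoid handling genes had a median of -0.998 at percentile 0.04 and -0.16 at the saline mixture, with 4 of 9 lower. Lrat, which stores retinol as esters, was 5.31-fold lower and the retinol carrier Rbp4 4.70-fold lower, and Aldh1a1 and Adh1 were the other lower members. The retinoic acid enzymes Cyp26b1 (4.53-fold) and Aldh1a3 (4.29-fold) were higher from low saline levels. Within alveolar fibroblast-like cells 0 of 8 retinoid genes were lower and 1 higher, with a median of -0.02. Within adventitial fibroblast-like cells 3 of 9 were lower, namely Lrat, Rbp4 and Adh1, and 2 higher, with a median of -0.34. The lower retinoid genes are thus not particular to alveolar cells. Among 12 lipid handling genes the lipoprotein lipase Lpl was higher (4.09-fold) and the lipolysis inhibitor G0s2 lower (4.66-fold), with a median of -0.17 at percentile 22.0 but 0.23 at the saline mixture.

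Signals from mesenchyme to epithelium split in both directions. Of 14 epithelial niche factors 5 were higher, namely Grem1, the neurotrophin Bdnf (6.24-fold), Igf1, Rspo3 and Il33, and 3 were lower, namely Bmp3 (ratio 0.338), Wnt2 (0.477) and Bmp4. Their median log2 ratio was -0.48 at percentile 0.41 over all mesenchymal cells and 0.26 at the saline mixture. Of 12 hedgehog, Wnt and Notch target genes Dkk2 (8.90-fold) and the secreted Wnt inhibitor Sfrp1 (8.73-fold, at 594 CPM in bleomycin) were higher, the hedgehog receptor Ptch1 was lower (ratio 0.478), and the median was -0.52 at percentile 0.51 and 0.03 at the saline mixture.

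Downstream of the leptin receptor, Lepr was the only one of 9 measured signalling genes to meet the rule. Jak2 had a ratio of 1.57, Ptpn1 1.42 and the feedback inhibitor Socs3 0.561, and the median log2 ratio was -0.27 at percentile 11.9 but 0.09 at the saline mixture. Of 10 genes typical of Lepr-positive stroma in bone marrow, Hp (8.38-fold), Lpl and the chemokine Cxcl12 were higher and angiopoietin 1, Angpt1, lower (ratio 0.490), with a median of -0.29 at percentile 7.78 and 0.0026 at the saline mixture.

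Acute phase and cytokine genes of inflammatory fibroblasts were in part higher. Of 11 inflammatory fibroblast markers 5 were higher and 0 lower, with a median log2 ratio of 0.67 at percentile 99.985 and 0.43 at the saline mixture. Haptoglobin, Hp, was at 52.9 CPM [51.0–54.7] and 443 CPM [440–447], lipocalin Lcn2 was 3.87-fold [3.76–3.97] and serum amyloid Saa3 3.81-fold [3.75–3.88] higher, while Cxcl5 had a ratio of 0.547 and Sod2 0.956. Of 13 complement and acute phase genes the higher 5 were the same genes as those inflammatory markers, Hp, Lcn2, Saa3, Serpina3n and Serpina3g, and the list's median was -0.15 at percentile 16.1 but 0.27 at the saline mixture, with C1ra at 0.625. Of 20 chemokines and cytokines, Cxcl13 (7.02-fold), Lif (5.36-fold), Cxcl2, Il33 and Cxcl12 were higher and 0 lower, with a median of 0.27 at percentile 97.9 and 0.28 at the saline mixture.

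Some interferon response genes were lower and some p53 target genes higher. Of 18 interferon response genes 5 were lower, 0 higher and 13 neither, with a median log2 ratio of -0.66 at percentile 0.02, and -0.10 at the saline mixture. Gbp2 had a ratio of 0.256 and the transcription factor Irf1 0.361, Psmb9, Irf9 and Gbp3 were the other lower members, and Isg15 was at 1.16. Of 18 p53 targets 8 were higher, 2 lower and 8 neither, with a median of 0.76 at percentile 100 and 0.48 at the saline mixture. Zmat3 (2.51-fold) and the kinase Plk2 (2.47-fold) led, the death receptor Fas (ratio 0.419) and Sesn1 (0.422) were lower, and the cell cycle inhibitor Cdkn1a was at 671 CPM [664–678] and 616 CPM [612–620], a ratio of 0.918 [0.907–0.929].

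Proliferation genes were higher. Of 16 proliferating cell markers 15 were higher, with a median log2 ratio of 1.95 at percentile 100. At the saline mixture, which holds the proliferating cluster at its saline part, the median was -0.55 and the ratio of Mki67 0.665. Mki67, a protein of dividing nuclei, was at 6.48 CPM [5.84–7.16] and 24.8 CPM [24.0–25.7], 3.83-fold [3.44–4.27] higher, and Pclaf was 8.45-fold and survivin, Birc5, 6.48-fold higher. The proliferating cluster was deep in both libraries, with median UMIs of 18033 and 22070, so doublets among it were not ruled out.

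Growth factor binding proteins differed in both directions. Of 15 IGF binding and growth factor genes 6 were higher, led by Igfbp2 (79.0-fold [60.05–106], from 0.867 CPM) and the matricellular Ccn4 (9.49-fold), and 2 were lower, Igfbp3 (ratio 0.197, and 0.227 at the saline mixture) and Igfbp6 (0.308), with a median log2 ratio of 0.47 at percentile 99.8 and 0.23 at the saline mixture. Of 20 immediate early genes, which respond to stimulation and to tissue digestion alike, Hspa1b (ratio 0.374), Egr1 (0.402), Atf3 and Jun were lower and 0 higher, with a median of -0.65 at percentile 0, and 0.03 at the saline mixture.

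Energy and housekeeping lists met the rule with 0 genes each. Over 16 glycolysis and hypoxia genes the median log2 ratio was -0.01 at percentile 45.7. Over 16 genes of endoplasmic reticulum stress it was 0.08 at percentile 64.7 but -0.07 at the saline mixture. It was 0.12 at percentile 76.7 over 20 ribosomal protein genes, and -0.11 at percentile 25.2 over 11 mitochondrially encoded genes. Of 11 adventitial fibroblast markers Cd248 (3.25-fold), Igfbp4 (2.41-fold), Col15a1 and Mfap5 were higher and Clec3b lower (ratio 0.297), with a median of -0.42 at percentile 2.15 and -0.12 at the saline mixture. Of 6 peribronchial markers P2ry14 (2.79-fold) and Fgf18 (2.55-fold) were higher, with a median of 0.14 at percentile 77.7 but -0.11 at the saline mixture. Of 9 pericyte markers Pdgfrb (3.08-fold) and Notch3 (2.33-fold) were higher and Pdzd2 lower (ratio 0.2502), with a median of -0.17 at percentile 27.7 but 0.06 at the saline mixture.

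Markers of the types counted as non-mesenchymal were scarce in the mesenchymal sums. The endothelial, lymphatic endothelial, neutrophil, lymphocyte, erythroid, Schwann cell and chondrocyte lists had 0 members at 10 CPM. The alveolar epithelial list had 2, Hopx at a ratio of 0.265 and surfactant protein Sftpc at 0.899 (20.7 CPM and 18.6 CPM), the airway list 1, Scgb1a1 at 0.834, which was 1.04 when cells were thinned to 2000 UMIs, and the macrophage list 2, Plac8 at 2.37 and Lyz2 at 1.29. The mesothelial list had 2, Upk1b at 0.423 and Nkain4 at 0.758.

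**Figure D3:**
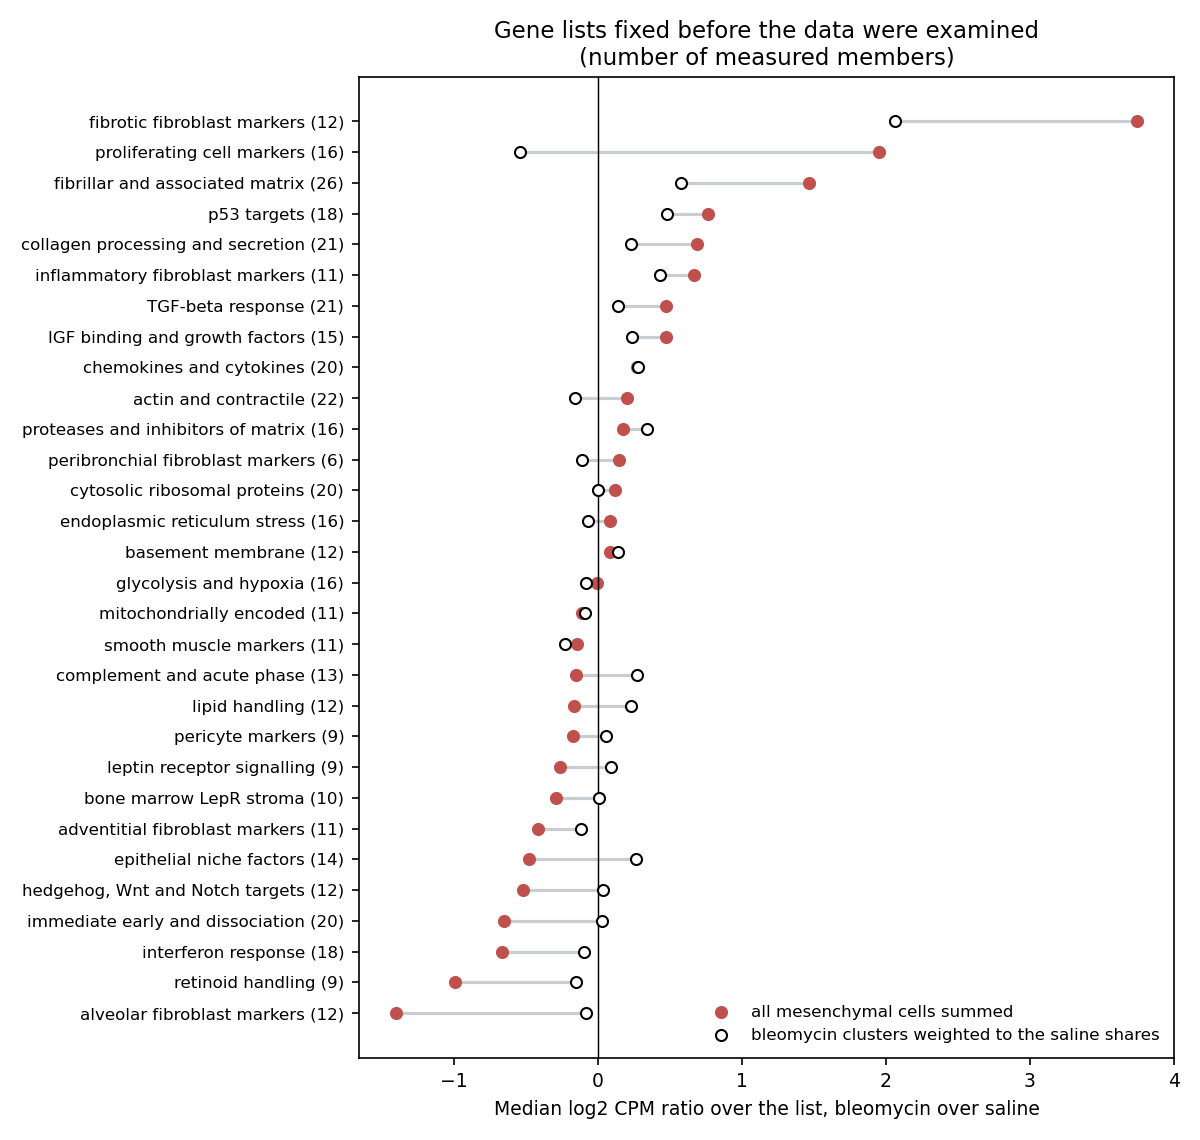
Median log2 ratio (bleomycin over saline) of each gene list with at least 6 measured members, over all mesenchymal cells and at the saline mixture of clusters, joined by a line per list. Fibrotic fibroblast markers lie farthest right at 3.75 and 2.06, and alveolar fibroblast markers farthest left at -1.41 but near 0 at the saline mixture.

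Within alveolar fibroblast-like cells the question was how cells of the same class differed between the libraries. These cells lay in clusters 2 and 3, with 5640 saline and 283 bleomycin cells. Cluster 2 held 3146 of the saline and 116 of the bleomycin cells and cluster 3 held 2494 and 167. By the size rule 117 genes were higher and 60 lower, against 209 and 128 when thinned to 2000 UMIs. With doublets kept the counts were 294 and 110. That setting added 66 saline and 0 bleomycin cells, but clustered all cells anew, and 362 bleomycin cells then took the alveolar name. In the main clustering 0 of the 12 alveolar fibroblast markers, which named the class, met the rule, with a median log2 ratio of -0.13. Some chemokines were among the higher genes, with Ccl5 at 3.69 and 43.4 CPM (11.8-fold [8.92–15.5]) and Cxcl9 at 39.6 and 228 CPM (5.76-fold [5.17–6.396]), and 6 of 19 chemokine and cytokine genes met the rule, with a median of 0.44. Nearly all UMIs of Ccl5 and Cxcl9 in these bleomycin cells lay in cluster 3, which Cxcl9 helps to define and where 3.76% of the cells of both libraries held it, so these ratios rest on few cells. Over all mesenchymal cells the Ccl5 CPM ratio was 2.74, and 0.913 without proliferating clusters. Serum amyloid Saa1 was 11.02-fold [7.90–15.2] higher, and 5 of 14 complement and acute phase genes were higher, with a median of 0.62. Of 19 interferon response genes 4 were higher here, namely Isg15, Irf7, Ifit1 and Ifit3, and the median was 0.18, against -0.66 over all mesenchymal cells.

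Fibrotic fibroblast markers were in part higher in these cells. Of 8 measured fibrotic markers 5 were higher, with a median log2 ratio of 2.37. Fst was 13.9-fold [9.63–20.1] higher, and Cthrc1 had a ratio of 110 [37.1–440] from 4 and 21 UMIs. Outside that list, Chl1 was 16.1-fold [10.6–24.4], Ereg 6.70-fold [4.90–9.06] and Aldh1a3 76.7-fold [39.8–159.5] higher. The ratio of Spp1 was 531 [264–1246]. In these bleomycin cells Cthrc1 was at 10.7 CPM and Spp1 at 104 CPM, below their levels of 31.9 and 908 CPM in the epithelial cluster of that library, so free RNA is open for both. Col1a1 had a ratio of 1.57 [1.504–1.65] and Col3a1 of 1.39 [1.34–1.43], which miss the rule, and 4 of 21 fibrillar matrix genes met the rule, with a median of 0.48. Of 17 p53 targets 3 met it, with a median of 0.32.

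The lowest genes in alveolar fibroblast-like cells were Tpm3-rs7 (ratio 0.0255 [0.00827–0.0595]), Cwc22 (0.0784 [0.0428–0.132]) and the growth factor carrier Igfbp3 (0.206 [0.170–0.248]). The matricellular protein gene Ccn2, a target of TGF-beta and of stretch, was at 666 and 170 CPM (0.255 [0.229–0.285]). Wee1 (0.278), Gfod2 (0.326), Fam189a2 (0.348) and Tmem100 (0.356) completed the 8 lowest. Lepr was at 48.8 and 32.7 CPM, a ratio of 0.670 [0.514–0.859], and Pdgfra at 0.893. Acta2 had a ratio of 0.956 [0.844–1.08] over the class but of 0.177 in cluster 2, from 8 bleomycin UMIs, and 0.942 in cluster 3. With 1956687 bleomycin UMIs in this class, genes near 10 CPM rest on few molecules.

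Matrix genes were also higher within classes other than the fibrotic one, most of all in peribronchial fibroblast-like cells. There, 19 of 23 measured fibrillar matrix genes and 12 of 21 collagen processing genes were higher, with median log2 ratios of 1.63 and 1.04, over 408 saline and 590 bleomycin cells. Col1a1 was 6.81-fold [6.30–7.37] and Postn 10.8-fold [9.003–13.1] higher. In smooth muscle-like cells (358 and 528) 15 of 23 matrix genes were higher, with a median of 1.32 and Col1a1 4.10-fold [3.84–4.38] higher. In adventitial fibroblast-like cells (1462 and 1212) 11 of 24 were higher, with a median of 0.92 and Col1a1 2.38-fold [2.35–2.42] higher. Proliferating cells (50 and 566) had 13 higher and 2 lower of 26, with a median of 0.86. Inflammatory fibroblast-like cells (174 and 4557) had 3 of 24 higher, with a median of 0.25. Free RNA and uncalled doublets in the bleomycin library were not tested for these matrix genes and are not ruled out.

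Adventitial fibroblast markers were also higher in part. In peribronchial cells 5 of 8 were higher (Ly6a, Cd248, Col15a1, Serpinf1 and Mfap5), with Clec3b lower and a median log2 ratio of 1.80. In smooth muscle cells 5 of 9 were higher (median 1.20). Free RNA and doublets were not tested for these markers either.

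Fibrotic markers were higher in several classes. In peribronchial cells 9 of 10 were higher (median log2 ratio 3.18), in smooth muscle cells 9 of 10 (2.31) and in adventitial cells 10 of 11 (2.19). Cthrc1 was 40.0-fold [26.7–62.7] higher in adventitial cells, at 2.27 and 90.7 CPM. In bleomycin it was at 143 CPM in cluster 6 of that class but at 24.5 CPM in cluster 5, below the 31.9 CPM of the epithelial cluster. It was 81.9-fold [22.6–678] higher in peribronchial cells from 2 saline UMIs. Spp1 in bleomycin was at 1054 CPM in peribronchial, 756 CPM in smooth muscle and 238 CPM in adventitial cells, against 908 CPM in the epithelial cluster and 22144 CPM in fibrotic cells. With levels near or below that of the epithelial cluster, free RNA is open for Spp1 in these classes too. The epithelial level may not measure free RNA alone, since alveolar cells of that library held 104 CPM [90.0–119] at a lower median depth of 6461 UMIs. An even load of free RNA would give these 3 deeper classes less than that, so only an uneven load stays open as the sole source.

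A few identity genes were lower within some of these classes. In smooth muscle-like cells Acta2 was at 19911 CPM in saline and 11144 CPM in bleomycin, a ratio of 0.560 [0.553–0.566], cardiac actin Actc1 was at 0.437 [0.422–0.452] and Synpo2 at 0.438 [0.401–0.478]. Acta2 there missed the size rule. Pericyte markers differed the other way, with 3 of 12 higher (Higd1b, Ndufa4l2 and Trpc6) and a median log2 ratio of 0.55. The pericyte list was the second-best match of this cluster (median log2 fold 1.67), and no cluster was named for pericytes. Pericytes in the class, in shares that differ between the libraries, are thus not ruled out. The 11 mitochondrially encoded genes had a median of -0.49 in smooth muscle-like cells. Of 12 smooth muscle markers in these cells 2 were lower and 1 higher, and of 22 contractile genes 1 was higher, 0 lower and 21 neither, with a median log2 ratio of -0.34. In adventitial cells Acta2 had a ratio of 1.59 [1.52–1.67], which misses the rule and was 1.39 in cluster 5 and 2.86 in cluster 6. Its share of cells at 2000 UMIs was 29.9% and 27.8% in cluster 5 but 13.3% and 24.3% in cluster 6. Higher in adventitial cells were 3 of 5 measured smooth muscle markers, Actg2, Tagln and Des (median 1.97), and in peribronchial cells Acta2 had a ratio of 1.17 [1.15–1.20]. Peribronchial cells had lower levels of their own markers Hhip (ratio 0.240 [0.230–0.2505]), Enpp2 (0.276 [0.260–0.292]) and Lgr5, out of 8 measured. The cluster of this class was led by the smooth muscle gene Cnn1, and the class held 338 and 434 cells at resolution 1 and 166 and 563 under the stricter filter, so smooth muscle cells within it are not ruled out. Inmt was at 1263 CPM in saline adventitial cells, a ratio of 0.184, but at 719 and 86.5 CPM in the epithelial cluster, so free RNA is open for part of it.

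Lepr was lower in adventitial cells, at 139 and 33.1 CPM (ratio 0.239 [0.213–0.266]), in peribronchial cells (0.368 [0.276–0.492]) and in smooth muscle cells (0.691 [0.524–0.913]). In proliferating cells the ratio was 0.199 [0.0954–0.454], from 10 saline UMIs, and in inflammatory cells it was 0.905 [0.586–1.47], a difference not detectable at this depth. Over all genes the size rule gave 249 higher and 286 lower in adventitial, 518 and 545 in peribronchial, 351 and 194 in smooth muscle, 239 and 150 in inflammatory and 321 and 658 in proliferating cells. The adventitial class lay mostly in cluster 5 in saline (1009 cells, against 453 in cluster 6) and in cluster 6 in bleomycin (697, against 515). Peribronchial cells had median depths of 3377 and 8948 UMIs.

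**Figure D4:**
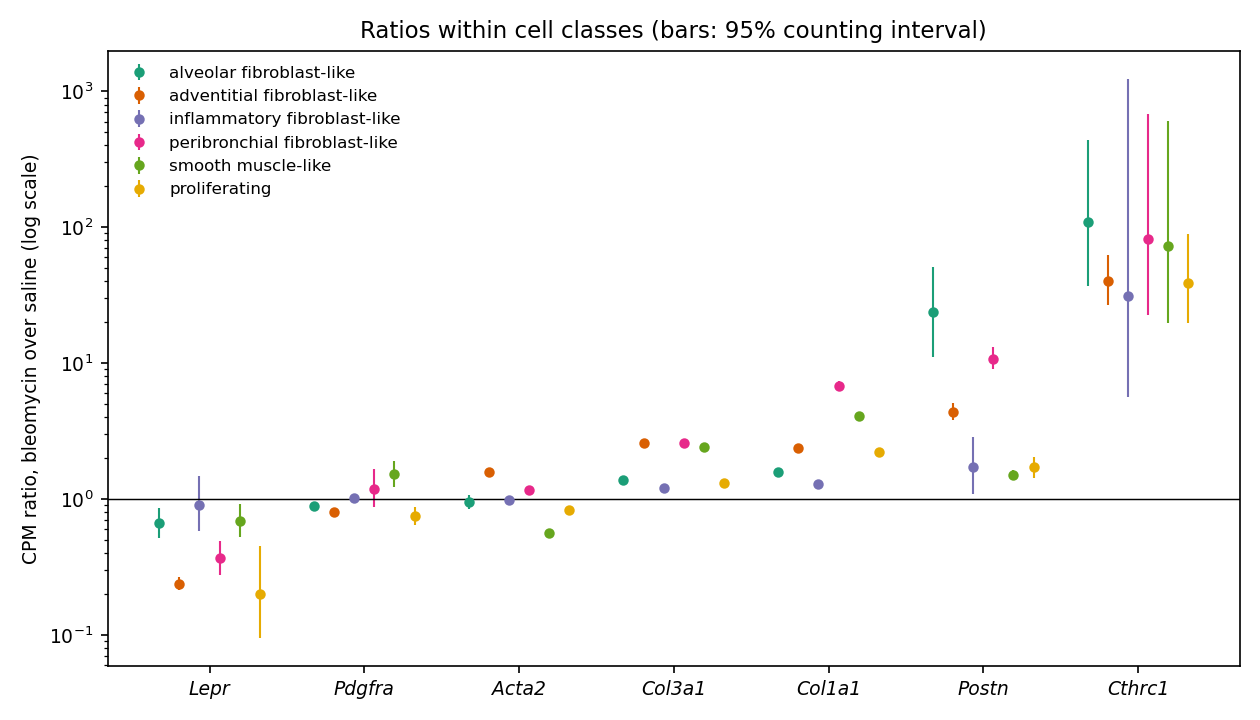
Ratio of CPM (bleomycin over saline, logarithmic axis) of Lepr, Pdgfra, Acta2, Col3a1, Col1a1, Postn and Cthrc1 in 6 mesenchymal classes, with 95% counting intervals as error bars. Cthrc1 lies above 10 in each class, though its level in alveolar (10.7 CPM) and inflammatory (16.4 CPM) bleomycin cells is below the 31.9 CPM of the epithelial cluster. Lepr lies below 1 in each class, but its interval includes 1 in inflammatory cells. Acta2 ranges from 0.560 in smooth muscle-like to 1.59 in adventitial fibroblast-like cells.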

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

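The tests of depth and of Y-linked genes for Xist, of handling for the immediate early genes, and both tests of free RNA were chosen only after the result was seen. The other tests were written down before their values were computed.

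Cells without Xist were far more frequent in the bleomycin library. Of bleomycin cells with at least 8000 UMIs 23.4% (1793 of 7677) had no UMI of Xist, the RNA that silences 1 X chromosome in females, against 1.94% of saline cells (50 of 2576). Depth argues little for it, since between 8000 and 12000 UMIs the shares were 24.3% [22.7–25.9] and 2.20% [1.60–2.96], and a male animal is argued against by 4 Y-linked genes at no more than 0.209 CPM in the cells without Xist. Cells with 1 X chromosome remain an explanation that the data allow. This was examined in mesenchymal bleomycin cells of at least 8000 UMIs outside clusters 1 and 4, 437 without and 1535 with Xist. Between them genes that escape silencing had a ratio of 0.731 [0.696–0.767], while 1076 other X-linked genes had 0.996. Within single clusters these other genes ran from 0.965 in cluster 6 to 1.08 in cluster 8. Whether the cells without Xist come from 1 of several pooled animals or arose within an animal stays open. Shares per cluster were not tested. In bleomycin they ran from 17.2% in cluster 7 to 25.3% in cluster 6 over mesenchymal clusters 1 and 3 to 9, and were 7 of 16 cells in cluster 2. In the epithelial cluster the share was 10.99% [5.40–19.3] in bleomycin and 16.7% [5.64–34.7] in saline (5 of 30). In mesothelial cells it was 17.4% in bleomycin and 0 of 25 in saline.

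Tpm3-rs7 and Cwc22 had among the lowest ratios of the genes lower in every cluster compared, and belong to no list. A difference in cell mixture is argued against by a median ratio of 0.0443 within clusters. A strain or donor variant is consistent with the highest ratio of either gene over 9 clusters, 0.223, but an effect of treatment common to all clusters would give the same. Reads shared between Tpm3-rs7 and its relative Tpm3 stay open, as the gain of Tpm3 was a median of 0.0997 of the loss of Tpm3-rs7, with values from -0.948 to 1.36 between clusters.

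The immediate early list had a median log2 ratio of -0.65 over all mesenchymal cells. A difference in handling would be likely to move all clusters alike, yet 3 of 9 clusters had a median above 0. Those were clusters 1, 2 and 3, which held few cells of 1 library (174 saline cells, and 116 and 167 bleomycin cells). The other 6 were below 0, among them the epithelial cluster at -0.21, so this count cannot decide on handling. A difference in cell mixture would give a median near 0 at the saline mixture, where it was 0.0254, but most of that weight lies in the same clusters 2 and 3. Handling that acts on all or on only some classes stays open, with medians of -0.56 in peribronchial cells and -0.51 in cluster 6 of the adventitial cells.

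Cthrc1 within adventitial, smooth muscle and peribronchial cells had at most 14.8 Spp1 UMIs per Cthrc1 UMI, below the 28.1 of fibrotic cells. This argues only against free RNA with the fibrotic ratio as the sole source of Cthrc1. The ratio in free RNA was not measured. In bleomycin it was 9.67 in alveolar cells, where free RNA is open for Cthrc1, 28.5 in the epithelial cluster and 95.7 in inflammatory cells. Free RNA with a lower ratio thus stays open for Cthrc1 in adventitial, smooth muscle and peribronchial cells. For Spp1 the highest level over these classes was 1.16 times that of the epithelial cluster, which leaves free RNA open.

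Acta2 differed between classes, its log2 ratio being 1.51 higher in adventitial than in smooth muscle cells (ratios of 1.59 and 0.560). This difference was not tested. Pericytes within the smooth muscle class are not ruled out, since their list was its second-best match. The adventitial ratio was 1.39 in cluster 5 and 2.86 in cluster 6, and the share of cells with Acta2 at 2000 UMIs differed by -2.08 points [-8.87 to 4.84] in cluster 5 and 10.99 points in cluster 6. In adventitial cells 3 of 5 smooth muscle markers were higher too (median log2 ratio 1.97). Clusters outside the comparisons were also larger in bleomycin, with mesothelial cells, led by Msln and Upk3b, at 1.17% of bleomycin and 0.507% of saline cells, and a cluster with immunoglobulin and myeloid genes at 0.710% and 0.217%.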

How the results depend on the processing

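Each group has 1 sample, so no replicate could be left out and animal-to-animal spread is unknown. No paired analysis was possible because each group holds a single library. Of the values for the main results under other settings 84 stayed within their limit and 41 did not, with 768 and 52 for single lists and 1024 and 450 for named genes, where 2 more turned direction. Genes near 10 CPM and small classes are limited by depth. Where no construction shows it, the cause was not tested.

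The main counts were 445 genes higher and 473 lower, and 117 and 60 within alveolar fibroblast-like cells. With no CPM minimum, which admits more genes, they were 1759 and 1897 (alveolar 385 and 198), with a minimum of 50 CPM 181 and 214 (alveolar 32 and 13), and at a fold of 1.5 985 and 1219. With doublets kept, where all cells were clustered anew and the class changed, the alveolar counts were 294 and 110. Thinned to 2000 UMIs they were 209 and 128. Scaling by the median of ratios gave 473 and 437, and the mean of per-cell CPM 414 and 376. Over all mesenchymal cells the Ccl5 CPM ratio of 2.74 was 0.913 without proliferating clusters and 0.628 with only Xist-positive cells, an alternative chosen after seeing the data.

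Shares of cells with a UMI are given as bleomycin minus saline in points, at 1000 UMIs, unthinned, and with at least 2 UMIs (4 genes for proliferation). For Lepr they were -4.54, -17.6 and -1.21 (main -8.25), for Cthrc1 9.28, 24.8 and 7.57 (main 13.3), for Acta2 15.5, 28.5 and 14.4 (main 18.0), and for proliferation 4.604, 11.5 and 4.19 (main 5.91).

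Class shares in the same points were -7.72 at resolution 0.25 and -2.43 at resolution 1 for adventitial cells (main -5.53). Alveolar cells had -47.3 at resolution 1, -30.3 with saline clusters as reference and -59.4 without size-rule genes (main -65.3). Inflammatory cells had 46.3 and 27.8 at those resolutions, 40.3 with doublets kept, 40.2 under the stricter filter, 2.25 with saline clusters as reference, which hold few such cells, and 30.2 without size-rule genes (main 43.5). Fibrotic cells had 25.1 without size-rule genes (main 18.8), and no saline cluster took that name. Peribronchial cells had 3.71 under the stricter filter and 0.259 at resolution 1 (main 0.974). Smooth muscle cells had 1.68 at resolution 1 and 0.446 without the 5% highest doublet scores (main 0.958). Proliferating cells had 4.35 without the 5% highest doublet scores and 3.60 without size-rule genes (main 5.06). Leaving out the highest doublet scores or the size-rule genes was chosen after seeing the data.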

Other observations

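Interferon response genes differed by class. None of the measured members was higher outside alveolar fibroblast-like cells, and 13 of 18 were lower in peribronchial cells (median log2 ratio -1.27), 13 of 18 in proliferating cells (-1.27), 5 of 18 in adventitial cells (-0.68), 4 of 15 in smooth muscle cells (-0.49) and 1 of 14 in inflammatory cells (-0.27). Gbp2 had a ratio of 0.232 in adventitial, 0.180 in peribronchial and 1.01 in alveolar fibroblast-like cells.

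IGF binding and growth factor genes had positive medians in all 6 classes, from 0.07 in inflammatory to 0.75 in smooth muscle cells. Igfbp3 was lower in smooth muscle (ratio 0.167), peribronchial (0.180) and adventitial cells (0.336). Haptoglobin, Hp, was 14.7-fold higher in adventitial and 7.36-fold higher in inflammatory cells.

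Besides Tpm3-rs7 and Cwc22, a few genes chosen after their values were seen had ratios of the same direction in all 9 clusters compared. The ratio of Gm8797 ranged from 9.95 to 22.2, that of Eif3j2 from 0.145 to 0.467 and that of Zbtb16 from 0.0673 to 0.4998. In bleomycin cells of at least 8000 UMIs outside clusters 1 and 4, Mpp7 had a ratio of 0.596 between cells without and with Xist.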
